A study of Mus musculus with 2 samples.

How the data were processed

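Small RNA libraries were made from total RNA of mouse liver with the SMARTer smRNA-seq kit and sequenced single-end, per the labels' protocols. The labels and the series description name different sequencer models. Reads were aligned against miRBase 22.1 and the mouse assembly mm10, then classed as 5p or 3p, per the labels' protocols, and cutadapt is named, without a version, in the submitters' processing notes. The aligner, the counting rule for reads that fit several miRNAs, any use of molecular identifiers and the statistical test are not given in the sources used here.

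The authors deposited 1 table of 281 mature miRNAs. It holds raw read counts per mature miRNA and library, and RPM values made by the authors from the same counts. The count divided by the RPM was constant within each library, giving library totals of 11432192 (wild type) and 18480608 (mutant) reads. What these totals count beyond the listed miRNAs is not given in the sources used here, and the listed rows hold 9350427 and 11313784 reads. The authors also deposited log2 normalized values, which equal log2 of 1 plus the RPM times a library factor of 1.46 (wild type) or 0.611 (mutant). The method behind the factors is not given in the sources used here. A signed fold score, an average log2 abundance and p-values per miRNA were deposited by the authors too. In the authors' deposited table the smallest absolute fold is 2.00, the largest p-value 0.0453 and the largest adjusted p-value 0.0817. The adjusted p-values imply that 646 miRNAs were tested, so 365 tested miRNAs are not listed and are not analysed here. Every listed miRNA has at least 1 read in both libraries. The authors' p-values come from 2 libraries and were not used.

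Each genotype is represented by 1 library, so the genotype cannot be told apart from the animal, the tissue sample or the library, and no test was run. The ratio of RPM was given an exact conditional binomial (Clopper-Pearson) 95% interval. Log2 fold changes were computed with a pseudocount of 0.5 reads scaled to library size, for 276 miRNAs with at least 10 reads over both libraries, and 5 miRNAs fell below this minimum. A miRNA was called higher or lower when it differed at least 2-fold and its interval excluded equality. Scaling by the sum of counts in the table had been fixed before the data were examined. Because the table holds only part of each library, the library totals behind the RPM were used in its place and the fixed scaling became an alternative. The arm was read from the miRNA's name, and 31 listed names carry none. Within a hairpin, names differing only in a copy number were summed per arm, and the log2 odds ratio of 5p against 3p was computed for 62 hairpins with at least 10 reads per arm, with 0.5 added to each count and a normal (Woolf) 95% interval in place of an exact one. Shares have Clopper-Pearson intervals. PCR copies are not independent molecules, so intervals cover counting error only. At these depths 3 reads correspond to 0.262 RPM in the wild type and 0.162 RPM in the mutant, so the wild-type value of a rare miRNA is the less precise.

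Intervals of medians are order-statistic (binomial) intervals over miRNAs or the range where there were too few, and miRNAs are not independent replicates. List medians were set against 10000 random lists of equal size drawn from the listed miRNAs and matched on mean expression. The 16 lists were fixed before the data were examined: hepatocyte-abundant, let-7, raised and lowered in liver tumours, miR-17-92 and paralogues, Dlk1-Dio3, H19-Igf2, Sfmbt2, blood cell, endothelial and mesenchymal, biliary and epithelial, muscle and neuroendocrine markers, miR-30, p53-responsive and noncanonical biogenesis. The miRNAs named were fixed by rule: the 8 highest and 8 lowest with at least 100 reads, the 6 most abundant in each library, the 5 hairpins with the lowest and the 5 with the highest 5p odds ratio with at least 50 reads per arm, up to 4 of the most abundant listed members of each list, and miR-122, let-7, miR-21a and miR-451a. Other miRNAs named were chosen after their values were seen.

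Hairpin coordinates come from GENCODE M21 on GRCm38, the same assembly as mm10, matched by gene symbol for 238 of 252 hairpins. Host genes are those overlapping on the same strand. Related names with counts within 5% of each other in both libraries (14 rows, such as miR-199a-3p and miR-199b-3p or miR-101a-3p and miR-101c) probably share reads and are uncertain.

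Alternatives were other scalings (the authors' factors, the sum of listed counts, edgeR's TMM and DESeq2 size factors on the listed rows, totals without the top miRNA of each library), pseudocounts, count minimums and fold limits. The calculations were tested on simulated counts for 281 rows of this comparison: 93.9% of intervals covered the true fold, and 98.0%, 86.0%, 88.0% and 100.0% of rows changed 8-fold, 2.5-fold, to 0.4 and to 0.125 were called, with 1 of 81 unchanged rows called. A log2 odds ratio set to -1 in 58 simulated hairpins was recovered as a median of -1.00. Of 100 random lists, 8.0% had a median outside the central 95% of matched lists. Python 3.11.15, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.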

Results

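Small RNA was sequenced from the liver of C57BL/6 mice aged 3 months. There was 1 library from a wild-type liver and 1 from a liver labelled as DICER1 mutant, in a model of DICER1 syndrome, a human tumour predisposition caused by variants of the gene. The deposited column headers name the mutant hDICER1_Mut, where the h may stand for the human gene. Dicer is the RNase III enzyme that cuts microRNA (miRNA) hairpins into mature strands: its RNase IIIb domain releases the strand from the 5′ side (5p) and its RNase IIIa domain the strand from the 3′ side (3p). The labels give neither the variant nor whether the mutant library came from tumour tissue, although the series description speaks of normal liver and liver cancer. The wild-type library held 11432192 reads and the mutant library 18480608, as implied by the deposited RPM values (read counts scaled to a common library total). The deposited table lists 281 mature miRNAs, which took 81.8% of the wild-type reads and 61.2% of the mutant reads. Every listed miRNA differed at least 2-fold in the authors' scaled values and had at least 1 read in each library. A limit on the authors' p-values probably applied as well. The comparisons below are therefore among listed miRNAs. DICER1 expression itself is not measured by these libraries. With 1 library per genotype there were no replicates, so no p-value was computed for any difference and all intervals, which are 95% intervals, cover counting error only.

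The first comparison asked which miRNAs differed between the mutant and the wild-type liver. Of 276 listed miRNAs with at least 10 reads in total, 171 were at least 2-fold higher in the mutant by RPM, 20 were at least 2-fold lower and 85 were called neither, where a higher or lower miRNA also had an interval excluding equality. Of these 85, 81 lay within 2-fold and 4 with few reads were more than 2-fold lower with an interval that included equality. Of the 8 highest miRNAs with at least 100 reads, 7 belonged to the imprinted Dlk1-Dio3 cluster, a group of hairpins expressed from the maternal chromosome. By RPM, 3 of 15 listed strands abundant in hepatocytes were at least 2-fold lower, namely miR-192-5p, miR-194-5p and miR-122-5p, and the other 12 lay within 2-fold, whereas all 15 were lower on the authors' scale and miR-192-5p alone with the sum of listed counts. By RPM, 8 of 11 listed biliary and epithelial strands were higher, as were all 6 listed endothelial and mesenchymal and all 6 listed blood cell strands. The endothelial and mesenchymal strands came from 3 of 8 hairpins on the list and the blood cell strands from 4 of 11. Of the higher strands, 5 biliary and epithelial, 2 endothelial and mesenchymal and 1 of blood cells stayed higher with DESeq2 size factors. Those factors were computed on the listed miRNAs alone, most of which were higher by RPM.

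Directions depended on the scaling, mostly near equality. With DESeq2 size factors, miRNAs well above equality changed direction too, such as let-7i-5p, 6.24-fold higher by RPM. The authors' values were scaled so that each mutant to wild-type ratio was 2.38-fold smaller than the RPM ratio, a shift of -1.25 on the log2 scale. On the authors' scale the same 276 miRNAs were split into 171 higher and 105 lower. The split was 152 and 105 with edgeR's TMM factors computed on the listed rows, 75 and 105 with DESeq2 size factors, and 171 and 58 when miR-192-5p and miR-22-3p were left out of the totals. With 2 libraries, DESeq2 size factors set the median ratio of the listed miRNAs to equality. As most of these were higher by RPM, some then turned lower by construction. TMM factors from the same rows also depend on which miRNAs were listed. Scaling to the sum of listed counts, which had been fixed before the data were examined, moved ratios the other way and gave 171 and 14. By RPM, listing began at 4.77-fold for higher miRNAs and at 1.19-fold higher for those the authors' deposited table gives as lower, and 18 of the latter had a higher RPM in the mutant.

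**Figure D1:**
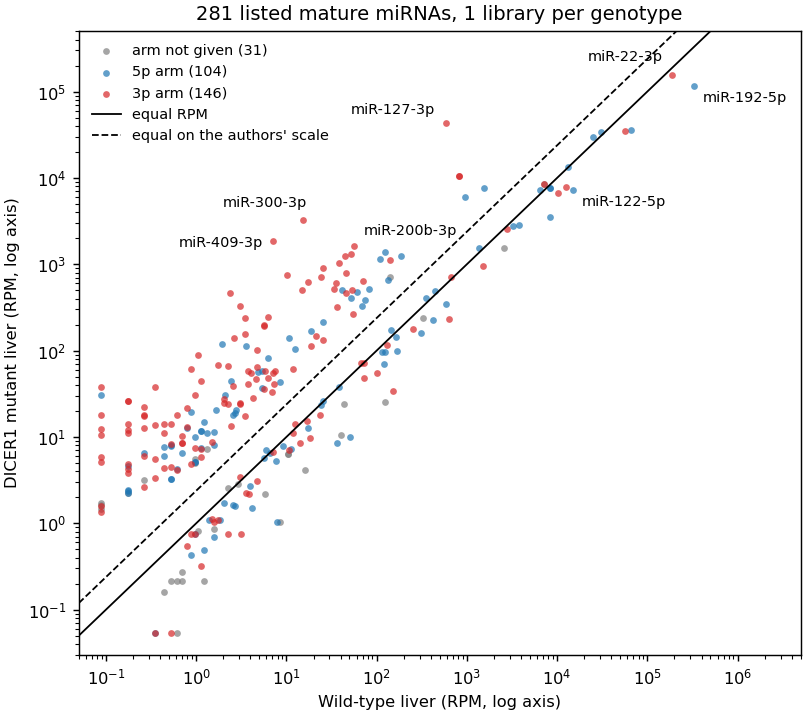
Abundance of the 281 listed mature miRNAs in the wild-type library (x axis, RPM, log scale) and in the DICER1 mutant library (y axis, RPM, log scale). Each point is 1 miRNA, coloured by hairpin arm. The solid line marks equal RPM and the dashed line equality on the authors' scale, 2.38-fold above it, and the empty band around the dashed line is the range in which miRNAs were not listed. miR-127-3p lies 74.1-fold above equal RPM.

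All 55 listed mature miRNAs of the Dlk1-Dio3 list, from 41 hairpins, were higher in the mutant by RPM, with log2 fold changes from 2.37 upwards. The lowest of them would turn lower with DESeq2 size factors, which shift all values by -2.73, and 41 stayed at least 2-fold higher. Their median by RPM log2 fold change was 4.89, with an interval of 4.45 to 5.41, whereas 95% of 10000 random lists of equal size and expression had medians between 2.48 and 3.52. These hairpins lie within 172 kb on chromosome 12, positions 109571990 to 109743795 of GRCm38 (mm10), those of miR-341 and miR-370 within introns of the noncoding gene Rian, others within Mirg and the rest outside annotated host genes. Together they accounted for 0.106% of wild-type reads and 5.69% of mutant reads, a 53.8-fold difference. The most abundant was miR-127-3p (chromosome 12, 109592846 to 109592915, outside annotated host genes), at 589 RPM in the wild-type and 43617 RPM in the mutant liver, 74.1-fold higher with an interval of 72.3 to 75.9. miR-409-3p, from an intron of Mirg at 109743158 to 109743236, was 257-fold higher (interval 207 to 324), from 82 reads to 34123. miR-300-3p, at 109724313 to 109724391, was 212-fold higher (interval 183 to 248), and miR-485-3p 199-fold higher (interval 137 to 302). miR-411-5p was 6.71-fold higher (interval 6.41 to 7.01). For cluster members with 1 to 3 wild-type reads the size was poorly fixed. miR-154-3p had 1 read against 701, a ratio of 434 with an interval of 77.6 to 17152, and miR-665-3p had 1 against 335, a ratio of 207 with an interval of 36.9 to 8209. miR-543-3p and miR-667-3p each had 2 wild-type reads and ratios of 150 and 149, with lower bounds of 41.4 and 41.1. The only miRNA among the 8 highest from outside the cluster was miR-582-5p, from an intron of Pde4d on chromosome 13, with 1 read against 568, a ratio of 351 with an interval of 62.8 to 13902. The cluster's median stayed above 0 on every scale tried, the lowest being 2.25 with DESeq2 size factors. The list does not hold miR-1247, from an exon of Dio3os on the same chromosome. Its 5p strand was 4.34-fold lower and its 3p strand 32.2-fold higher by RPM.

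**Figure D2:**
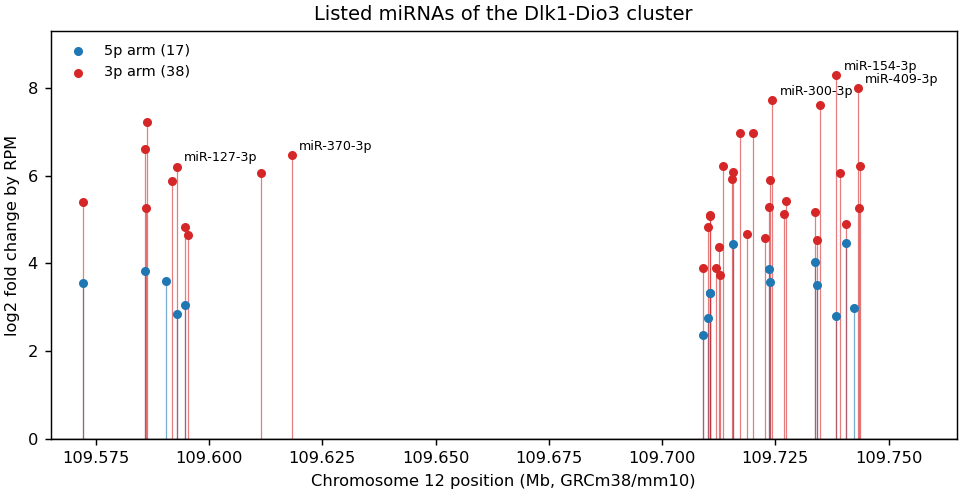
Log2 fold change by RPM (mutant over wild type, y axis) of the 55 listed Dlk1-Dio3 miRNAs against hairpin position on chromosome 12 (x axis, Mb, GRCm38/mm10). Blue points are 5p arms and red points 3p arms, each from 1 library per genotype. All points lie above 0, and the 3p arms, with a median of 5.42, lie mostly above the 5p arms, with a median of 3.52.

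Of 15 listed hepatocyte-abundant strands, 3 were at least 2-fold lower, none was 2-fold higher and 12 lay within 2-fold, among them miR-101a-3p and miR-802-3p with ratios of 1.16 and 1.08. The list's median was -0.64 (interval -0.87 to -0.28), against -0.28 to 3.18 for 95% of matched random lists. miR-192-5p (chromosome 19, 6264844 to 6264932, outside annotated host genes) was the most abundant wild-type miRNA, at 326657 RPM or 32.7% of all reads, and was 2.78-fold lower in the mutant, at 117503 RPM. Its cluster partner miR-194-5p was 2.40-fold lower (interval 2.37 to 2.42). miR-122-5p, the miRNA most characteristic of hepatocytes (chromosome 18, 65248861 to 65248926, in an exon of an annotated host gene), had 14951 RPM in the wild type and 7303 RPM in the mutant, 2.05-fold lower (interval 2.03 to 2.06). miR-148a-3p was 1.61-fold lower. miR-22-3p (chromosome 11, 75463716 to 75463810, in an exon of Mir22hg), the most abundant mutant miRNA at 153904 RPM, was 1.22-fold lower by RPM and turned higher when scaled to the sum of listed counts. On the authors' scale, where the list's median was -1.90, and with TMM or DESeq2 factors all 15 strands were at least 2-fold lower, and 10 were without the top miRNAs. When scaled to the sum of listed counts, with a median of -0.23, only miR-192-5p was lower, and miR-194-5p and miR-122-5p, at log2 -0.84 and -0.62, fell within 2-fold. Of 8 listed strands of the miR-30 family, the 3p strands miR-30b-3p and miR-30d-3p were 5.15-fold and 9.13-fold higher and the other 6 were called neither. Of those, miR-30f had 8 reads against 5, a log2 fold change of -1.27 with an interval that included equality, and the others lay within 2-fold. Among them, miR-30a-5p, miR-30c-5p, miR-30d-5p and miR-30e-5p had ratios of 0.538, 0.860, 1.13 and 0.927. The family's median was 0.03 by RPM and -1.22 on the authors' scale, and it was also below 0 with TMM factors, with DESeq2 size factors and without the top miRNAs. On the authors' scale 2 strands were higher and 6 lower, with TMM factors 1 and 6, and with DESeq2 size factors 0 and 6. With the sum of listed counts 2 were higher and 0 lower.

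Of 11 listed biliary and epithelial marker miRNAs, 8 were at least 2-fold higher and 3 lay within 2-fold. Of the 8 higher, 7 were of the miR-200 family and the other was miR-205-5p, with 8 wild-type reads. miR-200b-3p (chromosome 4, 156055681 to 156055750, in an intron of Ttll10) was 28.8-fold higher (interval 26.6 to 31.2) and miR-141-3p 27.5-fold higher (interval 25.0 to 30.3). These miRNAs maintain epithelial identity by repressing Zeb factors. The skin and epithelial miRNA miR-203-3p was 1.56-fold lower and miR-31-5p had a ratio of 1.11, which turned lower on the authors' scale. The list's median of 3.17 lay inside the range of matched random lists, 0.15 to 4.45. It was 4.12 with at least 100 reads and 0.50 with DESeq2 size factors. All 6 listed endothelial and mesenchymal marker strands were higher, with a median of 3.69 (random range -0.49 to 4.47). They came from 3 of the list's 8 hairpins, miR-199a, miR-199b and miR-214, so the list's other hairpins are not described. miR-199a-3p was 12.8-fold higher (interval 12.5 to 13.1), miR-199a-5p 10.5-fold and miR-214-3p 17.1-fold. miR-199a-3p and miR-199b-3p carry identical counts and cannot be told apart. All 6 listed blood cell marker strands were higher, with a median of 2.87 (random range -0.33 to 4.90). They came from 4 of that list's 11 hairpins. The pan-leukocyte miR-142a-5p reached 7725 RPM, 4.95-fold higher (interval 4.87 to 5.02), miR-142a-3p was 7.81-fold higher, the myeloid miR-223-3p 10.1-fold and the lymphoid miR-150-5p 4.78-fold. With DESeq2 size factors miR-142a-5p and miR-150-5p turned lower and the list's median was 0.15.

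Of 15 listed strands from hairpins reported as raised in liver tumours, 14 were higher, among them the DNA damage response miRNA miR-34a-5p at 8.40-fold (interval 7.46 to 9.48), miR-301a-3p at 9.44-fold and miR-146b-5p at 7.97-fold. The abundant oncogenic miRNA miR-21a-5p had a ratio of 1.13 by RPM and a signed fold of -2.10 in the authors' deposited table. With DESeq2 size factors 5 of the 15 were higher and the list's median was 0.27. By RPM the median of 2.99 was inside the random range of 0.02 to 3.94. Of 35 strands from hairpins reported as lowered in liver tumours, 16 were higher, 4 lower and 15 within 2-fold, with a median of 0.21 by RPM that was below 0 on the authors' scale (-1.04), with TMM factors (-1.23), with DESeq2 size factors (-2.51) and without the top miRNAs (-0.37). It was 0.63 with the sum of listed counts and 1.48 with at least 100 reads, and 19 strands were lower on the authors' scale and 2 with the sum of listed counts. Several of these hairpins are also in the hepatocyte or the endothelial and mesenchymal list. Of the miR-17-92 cluster and its paralogues, which promote cell division, the 6 listed strands with at least 10 reads were all higher. Their median was 3.27 (random range -0.29 to 4.98). They came from 5 of the list's 13 hairpins, and 5 of them were 3p strands. No strand from 1.19-fold to 4.77-fold higher by RPM was listed, so these strands do not describe the whole list. The strand miR-19b-1-5p, below the minimum of 10 reads, had 4 reads in the wild type against 1, and with it the median was 2.81. Examples were miR-18a-5p at 13.3-fold (interval 11.1 to 16.1), miR-106b-3p at 7.04-fold and miR-20a-3p at 27.1-fold. miR-17-3p was 5.60-fold higher and turned lower with DESeq2 size factors, with which 3 of the 6 stayed higher. Of the 10 listed p53-responsive strands, 5 were higher, 2 lower and 3 within 2-fold, with a median of 1.58 that was 0.10 with at least 100 reads and turned to -1.14 with DESeq2 size factors. With DESeq2 size factors 1 was higher and 5 lower, and on the authors' scale and with TMM factors 5 and 5. miR-107-3p had a ratio of 1.07 by RPM and was lower on the authors' scale. The let-7 family, which restrains growth, had 6 of 9 listed strands higher and 3 within 2-fold. Their median of 2.33 (random range -0.40 to 3.87) turned to -0.40 with DESeq2 size factors, where none was 2-fold higher. These strands came from 6 of the list's 11 hairpin names. No strand of let-7a, let-7b or let-7d was listed, and of let-7c only the 3p strand was. The median therefore describes the listed strands and not the whole family. let-7i-5p was 6.24-fold higher (interval 6.12 to 6.37), let-7e-5p 4.82-fold and let-7j 5.02-fold. let-7f-5p had a ratio of 1.02 by RPM and was lower on the authors' scale, and let-7g-5p was 1.32-fold lower by RPM. Of the 3p strands, let-7g-3p had a ratio of 0.917, and let-7i-3p, let-7e-3p and let-7c-1-3p were 7.72-fold, 7.85-fold and 5.14-fold higher. With DESeq2 size factors let-7i-5p, let-7e-5p, let-7j and let-7c-1-3p turned lower. In the Sfmbt2 cluster all 5 listed strands were higher at low counts (median 3.47, random range -0.82 to 3.83), with identical counts for miR-467a-5p and miR-467b-5p (5.34-fold, lower with DESeq2 size factors) and for miR-669a-3p and miR-669o-3p (12.1-fold). None of the 5 stayed 2-fold higher with DESeq2 size factors. Only single strands were listed for the smaller lists. The muscle miRNA miR-133a-3p was 1.62-fold lower at 41 reads in each library, and miR-375-3p and miR-7a-1-3p, of neuroendocrine cells, were 6.62-fold and 7.64-fold higher by RPM and within 2-fold with DESeq2 size factors. Strands of the H19-Igf2 list and of the hairpins with noncanonical biogenesis, miR-451a among them, are not analysed here.

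**Figure D3:**
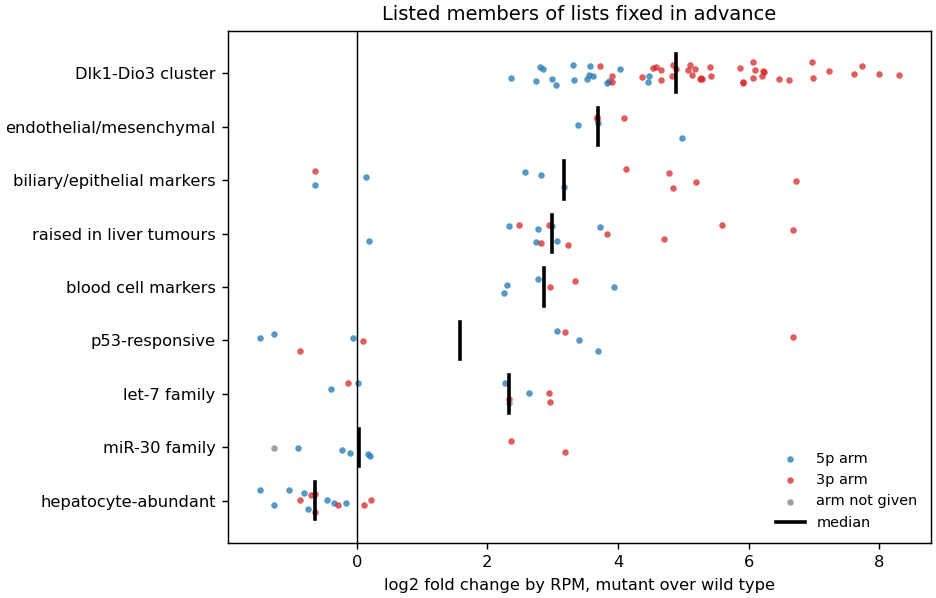
Log2 fold change by RPM (mutant over wild type, x axis) of the listed members of 9 miRNA lists (y axis) that were fixed before the data were examined. Each point is 1 mature miRNA coloured by arm, from 1 library per genotype, and black bars are list medians. The hepatocyte-abundant list has a median of -0.64 and the Dlk1-Dio3 list one of 4.89.

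The lowest miRNAs were rare. The 8 lowest with at least 100 reads were miR-692, 8.34-fold lower (interval 5.07 to 14.4), miR-592-5p, 7.74-fold (interval 4.69 to 13.4), both strands of miR-1948 at 5.00-fold (5p) and 4.41-fold (3p), miR-3470b at 4.81-fold, miR-1247-5p at 4.34-fold, miR-690 at 3.88-fold and miR-3470a at 3.82-fold. None exceeded 152 RPM in either library. The names miR-692, miR-3470b, miR-690 and miR-3470a carry no arm, and the hairpins mir-692-2 and mir-692-3 overlap exons of Ftl2-ps and Ftl1-ps1. Whether the reads of these names are hairpin products was not examined. Of the 20 lower miRNAs, 7 had fewer than 100 reads in total.

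The second comparison asked whether the strands from the 5′ and 3′ sides of hairpins differed in their response, as the labels state that reads were classed by arm. By RPM, 3p strands were higher in the mutant more often and by a larger ratio than 5p strands. Of 144 listed 3p strands, 107 (74.3%) were at least 2-fold higher and 5 lower, and of 103 5p strands, 55 (53.4%) were higher and 9 lower. With DESeq2 size factors 62 and 13 were higher and 37 and 48 lower. The median log2 fold change was 3.48 for 3p strands (interval 3.00 to 3.91) and 2.33 for 5p strands (interval 0.17 to 2.74), the latter turning to -0.37 with DESeq2 size factors. The 3p median lay above the 2.63 to 3.09 that held 95% of random lists matched on expression, and the 5p median was at their lower edge (2.33 to 3.02). The difference between the medians was -1.14. It was -0.75 among hairpins with both strands listed, and -2.68 without the Dlk1-Dio3 hairpins, where the 5p median fell to 0.18, below the range from 1.19-fold to 4.77-fold higher in which no miRNA was listed. Among listed reads with an arm, the 5p share was 64.8% in the wild type and 49.3% in the mutant. Without miR-192-5p the shares were 40.9% and 37.0%. Such shares rest on a few abundant miRNAs and do not describe most strands. miR-127-3p alone held 6732 of 3246792 3p reads in the wild type and 806063 of 5635222 in the mutant.

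Within hairpins, where scaling cancels in the ratio, the 5p strand was lower relative to its 3p partner in most listed cases. The authors' scaling still decided which hairpins entered, as no strand from 1.19-fold to 4.77-fold higher by RPM was listed. Hairpins with strands on both sides of this range entered only with a large shift. One was miR-30d, with log2 fold changes of 0.17 (5p) and 3.19 (3p). Of 62 hairpins with both strands listed and at least 10 reads per strand, 35 had a lower 5p to 3p ratio in the mutant with an interval excluding equality, 2 had a higher one, and for 25 the interval included equality. The median log2 odds ratio was -0.53, with an interval of -1.31 to -0.20, and 50 of 62 hairpins lay below 0. When the dominant strand was set by the summed reads of both libraries, 17 of 27 hairpins dominated by the 5p strand and 18 of 35 dominated by the 3p strand had a lower ratio, with medians of -0.66 and -0.40. When it was set by the wild-type library alone, these were 22 of 33 and 13 of 29, with medians of -0.95 and -0.20. Both divisions use reads that enter the ratio. The 14 Dlk1-Dio3 hairpins had a median of -1.78 (interval -2.74 to -1.15), and 10 of them had a lower ratio. Without these hairpins the median was -0.25 (interval -0.66 to -0.08), with 25 of 48 lower and 2 higher. The 48 include miR-1247, which is not on the Dlk1-Dio3 list.

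The largest shift was in miR-1247, on chromosome 12 at 110278048 to 110278129 in an exon of Dio3os. Its 5p strand made up 97.4% of its reads in the wild type (exact interval 95.5 to 98.7) and 21.4% in the mutant (interval 18.5 to 24.6), a log2 odds ratio of -7.06 (interval -7.94 to -6.18). In miR-99a (chromosome 16, 77598936 to 77599000, in an intron of Mir99ahg) the 5p share was 91.3% in the wild type and 44.1% in the mutant, with a log2 odds ratio of -3.73 (interval -3.88 to -3.57). Its 3p strand was 15.1-fold higher and its 5p strand had a ratio of 1.14. As a hairpin enters only when both strands are listed, hairpins with 1 unlisted strand are not counted. miR-154 had 96.9% and 33.6% of reads on the 5p strand, a log2 odds ratio of -5.38 (interval -7.75 to -3.01). The tumour-suppressive miR-26a and miR-34a kept almost all reads on the 5p strand, with log2 odds ratios of -3.71 (interval -4.13 to -3.29) and -3.48 (interval -5.81 to -1.16), the last resting on 1 wild-type read of miR-34a-3p. miR-26a-5p itself had a ratio of 1.19 by RPM and was lower on the authors' scale. Of 6 hepatocyte-abundant hairpins, 5 had a lower ratio, and their median was -0.22. miR-101a, which shares 3p reads with miR-101c, had a log2 odds ratio of -0.66, miR-192 -0.60 (interval -0.72 to -0.48), miR-148a -0.06 (interval -0.11 to -0.01) and miR-22 -0.06 (interval -0.16 to 0.04).

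In the opposite direction, miR-29c had a higher 5p to 3p ratio, with a log2 odds ratio of 0.78 (interval 0.43 to 1.13), and so did miR-199b, at 1.30 (interval 0.86 to 1.75). The 3p counts of miR-199b are those of miR-199a as well, so its ratio is uncertain. miR-582, at 2.15 (interval -0.22 to 4.52), miR-497a, at 0.72 (interval -0.16 to 1.60), and miR-342, at 0.69 (interval -0.45 to 1.84), had intervals that included equality.

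**Figure D4:**
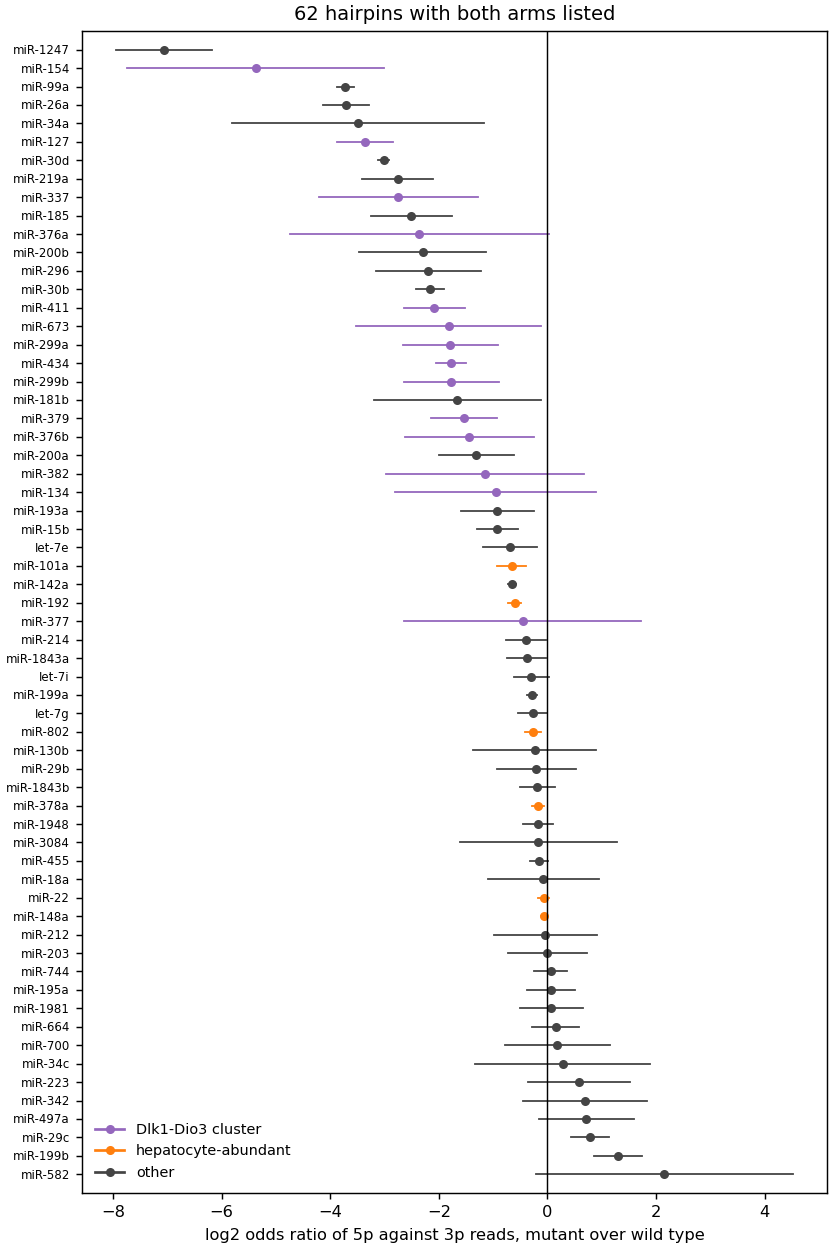
Log2 odds ratio of 5p against 3p reads, mutant over wild type (x axis), for each of 62 hairpins with both strands listed (y axis). Points are estimates from 1 library per genotype and lines their 95% intervals from counting error. Values below 0 mean a smaller 5p share in the mutant: 50 of 62 points lie there, the lowest being miR-1247 at -7.06.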

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

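Scaling by the library totals behind the RPM was chosen after the data were seen, in place of the sum of listed counts, which had been fixed before. Also chosen after were the authors' scaling, the dominant strand in the wild type, and the settings without the Dlk1-Dio3 hairpins, without hairpins that share reads, without miR-192-5p and with 1 of each set of identical counts. No paired analysis was possible because each group has 1 sample, and no replicate could be left out. A scaling shifts the log2 fold change of every miRNA alike, by -1.44 (TMM), -2.73 (DESeq2), -0.58 (without the top miRNAs), -1.25 (authors) or 0.42 (sum of listed counts), and this construction moves the counts and medians below. TMM and DESeq2 factors came from the listed miRNAs, most of them higher by RPM. Calls lost with these factors therefore follow in part from the listing. Of 390 values of named miRNAs under alternatives, 38 changed sign, 9 of them of miRNAs that were at least 2-fold higher by RPM and 29 of miRNAs within 2-fold. In all, 106 values stayed within the counting interval of the RPM ratio, 65 of them with the pseudocount of 5. Of the scalings, the sum of listed counts kept 17 of 65 values there, totals without the top miRNAs 14, TMM 5 and the authors' factors 5. With DESeq2 size factors 56 moved outside it and 9 more reversed direction. The median log2 odds ratio within hairpins, not divided by dominant strand, lay below 0 under every setting tried, the closest being -0.25 without the Dlk1-Dio3 hairpins, and 25 to 35 hairpins had a lower 5p share. None of these settings changed which strands were listed. Counts pooled over hairpins gave -1.09, but this value is not a ratio within hairpins. It depends strongly on miR-192-5p, which held 3734406 wild-type and 2171524 mutant reads, so it does not bear on the other hairpins. With the dominant strand in the wild type, the medians were -0.95 (5p) and -0.20 (3p). Counting error is large for miRNAs with few reads, among them the 33 higher miRNAs with 1 to 3 wild-type reads.

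With TMM factors 105 miRNAs were lower (48 of 5p and 37 of 3p), the 3p median was 2.06, and list medians were -2.09 (hepatocyte), 1.55 (raised in tumours), -1.23 (lowered in tumours), 1.83 (miR-17-92), 3.51 (Dlk1-Dio3), 2.12 (Sfmbt2), 1.43 (blood), 2.25 (endothelial and mesenchymal) and -1.41 (miR-30). With DESeq2 size factors 75 were higher (13 of 5p, 62 of 3p) and 105 lower (48 of 5p, 37 of 3p), the 5p median reversed to -0.37 and the 3p median was 0.79. Of the marker strands 5 biliary, 2 endothelial or mesenchymal and 1 of blood cells were still higher, but none of the neuroendocrine ones. Of the other lists 41 Dlk1-Dio3, 3 miR-17-92, 5 raised-in-tumour, 6 lowered-in-tumour and 1 p53-responsive strands were still higher, but none of let-7, Sfmbt2 or miR-30. List medians were then -3.37 (hepatocyte), -0.40 (let-7), 0.27 (raised), -2.51 (lowered), 0.55 (miR-17-92), 2.25 (Dlk1-Dio3), 0.86 (Sfmbt2), 0.15 (blood), 0.96 (endothelial and mesenchymal) and -2.69 (miR-30). Of miRNAs at least 2-fold higher by RPM, those that changed sign were let-7c-1-3p (-0.36), let-7e-5p (-0.46), let-7i-5p (-0.083), let-7j (-0.40), miR-142a-5p (-0.42), miR-150-5p (-0.47), miR-17-3p (-0.24), and miR-467a-5p and miR-467b-5p (-0.31). Of those within 2-fold, let-7f-5p (-2.70), miR-107-3p (-2.63), miR-21a-5p (-2.54), miR-26a-5p (-2.48), miR-30d-5p (-2.55) and miR-31-5p (-2.58) turned lower with these factors, and also with TMM, without the top miRNAs and on the authors' scale. Without the top miRNAs 58 were lower (23 of 5p, 20 of 3p), the 3p median was 2.91, and list medians were -1.23 (hepatocyte), 2.41 (raised), -0.37 (lowered), 4.33 (Dlk1-Dio3) and 3.10 (endothelial and mesenchymal). On the authors' scale 105 were lower (48 of 5p, 37 of 3p), the 3p median was 2.25, and list medians were -1.90 (hepatocyte), 1.74 (raised), -1.04 (lowered), 2.02 (miR-17-92), 3.69 (Dlk1-Dio3), 2.31 (Sfmbt2), 1.62 (blood) and 2.44 (endothelial and mesenchymal). With the sum of listed counts 5 5p strands were lower, the 5p median was 2.74, and list medians were -0.23 (hepatocyte) and 3.84 (Sfmbt2), and let-7g-3p (0.29), let-7g-5p (0.02), miR-22-3p (0.13), miR-30c-5p (0.20) and miR-30e-5p (0.31) turned higher.

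A pseudocount of 5 gave medians of 4.43 (Dlk1-Dio3) and 2.36 (Sfmbt2) and 4 hairpins with a higher 5p share. With at least 100 counts 13 miRNAs were lower, 2 of them 3p strands, and list medians were 1.48 (lowered in tumours), 0.10 (p53), 4.12 (biliary and epithelial) and 0.17 (miR-30). With a limit of 1.5-fold 43 were lower (17 of 5p, 16 of 3p) and with 4-fold 8 (3 of 5p, 2 of 3p), as the limit itself sets. Without the Dlk1-Dio3 hairpins 69 3p strands were higher, from fewer miRNAs, and the medians were 2.87 (3p) and 0.18 (5p), a difference of -2.68, against -0.75 among hairpins with both strands listed. No listed ratio lies between 1.19-fold and 4.77-fold higher, so the 5p median moves far when miRNAs are left out. Without hairpins that share reads 1 hairpin had a higher 5p share, and without miR-192-5p the 5p share of reads was 40.9% in the wild type and 37.0% in the mutant. The latter shares still include miR-127-3p, with 6732 wild-type and 806063 mutant reads.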

Other observations

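The families, hairpin groups and tests in this part were chosen after the values were seen, whereas the marker lists and their members had been fixed before. Outside the lists, the imprinted miR-296 and miR-298 hairpins, neighbours on chromosome 2, stood out at low wild-type counts: miR-296-3p was 85.0-fold higher in the mutant by RPM (interval 48.5 to 165), miR-298-5p 62.3-fold (interval 41.1 to 99.7) and miR-296-5p 18.1-fold (interval 12.4 to 27.4). All 7 listed strands of the miR-200 family, which are also on the biliary and epithelial list, were higher, with a median log2 fold change of 4.78. Among them were miR-200c-3p at 107-fold (interval 76.5 to 153) and miR-429-3p at 36.5-fold (interval 31.7 to 42.2). All 6 listed strands of the miR-15 family were higher, with miR-195a-5p at 11.2-fold, and so were all 6 of the miR-181 family, with miR-181c-3p at 33.9-fold. The lowest strands of these families, at log2 2.58, 2.40 and 2.59, would turn lower with DESeq2 size factors, a shift of -2.73. Of 6 listed strands of the miR-29 family none was 2-fold higher, and miR-29c-3p was 2.69-fold lower (interval 2.59 to 2.80).

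Among hairpins with only 1 side listed, 63 of 81 strands from the 3p side were higher and 3 lower, with a median of 3.59, and 19 of 40 from the 5p side were higher and 5 lower, with a median of 0.16. Without the Dlk1-Dio3 hairpins, 39 of 57 and 16 of 37 were higher. Of the 20 lower miRNAs, 6 have names without an arm.

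The lower 5p share within hairpins was set against a technical explanation. A library that favours all 3p strands alike would give every hairpin a similar shift, whereas the median log2 odds ratio was -1.78 in the Dlk1-Dio3 hairpins (interval -2.74 to -1.15) and -0.25 in the others (interval -0.66 to -0.08). The others include miR-1247 of Dio3os, at -7.06. Hairpins with a strand from 1.19-fold to 4.77-fold higher by RPM did not enter, so the listing also shaped these medians. Their contrast alone therefore cannot decide the explanation. Single hairpins differed beyond counting error, such as miR-99a at -3.73 (interval -3.88 to -3.57) and miR-148a at -0.06 (interval -0.11 to -0.01). A bias that differs between hairpins stays open as well. Reduced cutting by the RNase IIIb domain may lower 5p strands and remains an untested hypothesis, since genotype, animal, possible tumour state and library cannot be separated with 1 library each and the variant is not stated in the labels.

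By RPM, all 6 listed blood cell strands, all 6 listed endothelial and mesenchymal strands and 8 of 11 biliary and epithelial strands were higher in the mutant. Of 15 hepatocyte strands, 3 were lower. The endothelial and mesenchymal strands came only from miR-199a, miR-199b and miR-214. A lower share of hepatocyte RNA alone could raise all other markers alike. The medians of the 3 marker lists differed by at most 0.82 on the log2 scale, but with so few strands their intervals spanned almost all members, so this comparison could not decide. Single ratios lay far apart, from 0.641 for miR-203-3p, 1.11 for miR-31-5p and 0.619 for the muscle miR-133a-3p to 4.95 for miR-142a-5p and 28.8 for miR-200b-3p. No ratio from 1.19 to 4.77 was listed, so the gap between the low and the high markers follows from the listing. Above that range, miR-142a-5p (interval 4.87 to 5.02) and miR-200b-3p (interval 26.6 to 31.2) still differed beyond counting error, which goes against an equal rise of these strands. The explanation was left open because miR-203-3p and miR-31-5p had 1491 and 447 RPM in the wild type and may have another source there, miR-133a-3p had 41 reads, and no replicate gives the spread.

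Hairpins differed in how far the 5p share was lower. Across hairpins, which are not independent replicates, Spearman's rho of the log2 odds ratio was -0.00224 with the fold change of the 5p strand and -0.565 with that of the 3p strand. Both strands are part of the odds ratio, which keeps open whether the shift may be larger in hairpins that were higher in the mutant.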
